A study of Mus musculus with 6 samples.

How the data were processed

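Gene expression was measured by RNA sequencing of total RNA from proB cells sorted out of mouse bone marrow, with 6 libraries covering 3 genotypes and 2 Hardy fractions, 1 library for each combination. The genotypes were wild type (wt), a mutant of zinc finger 1 of Ikaros (the ZnF1 mutant) and a mutant of zinc finger 4 (the ZnF4 mutant). The fractions were B and the pool of C and C', called fraction C. Libraries were made with an Illumina TruSeq kit, per the labels' protocols. Groups were taken from the sample titles and the genotype and stage labels.

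The values are RPKM (reads per transcript length and per library size) computed by the authors, per the file headers, for each RefSeq transcript and rounded to 0.1. TopHat, bedtools and genome build mm9 are named, without versions or roles, per the submitters' processing notes. Which reads entered the denominator, whether strand was used and how reads shared by transcripts were divided are not given in the sources used here. Genes such as Gapdh, Pgam1, Eno1 and Hmgb1, which have near-identical copies elsewhere in the genome, stood at or near 0, so values of genes with such copies are uncertain and a 0 means only that a gene is listed at 0. The uncertain genes include the globins Hba-a1 and Hbb-b1 and the entry Beta-s, and also Ptma, Hmgb2, Cbx3, Rplp1, small nucleolar RNAs and microRNAs. Xist and Tsix lie antisense to each other and cannot be told apart without strand.

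The table held 26532 entries, 1 of them without a gene name and left out, and 0 columns of other samples. The remaining 26531 transcripts carried 22098 symbols, and each of the 3305 symbols with several transcripts was represented by the transcript with the highest mean RPKM. Genes with a mean of at least 1 RPKM over the 6 libraries were kept, which left 10943. Read numbers were not recovered. Tested on low values of short transcripts, 43.2% to 63.0% of the values per library could be whole reads, against 32.3% to 35.4% by chance. Depth is therefore unknown, and no counting interval or floor is given. RPKM sums per library, which depend on transcript lengths and on shared reads, were 269419.7 (wt), 296548.6 (ZnF1) and 262648.6 (ZnF4) in fraction B and 288789.7, 355822.4 and 284200.1 in fraction C.

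Folds were taken as log2(RPKM + 1) differences between a pair of libraries and printed as fold sizes on that scale, which understates the change of genes with low values. Genes at least 2-fold apart were counted in each direction, per fraction and in both fractions together, beside n1 × n2 / N, the number expected of independent lists. For models across genes, limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3) was fitted to log2(RPKM + 1) of all 6 libraries with genotype and fraction as additive terms. A Benjamini-Hochberg adjusted p under 0.05 was taken as passing. The model leaves 2 residual degrees of freedom, its spread comes from genotype effects that differ between fractions, and its p-values are two-sided. Nothing in the labels says how many animals entered a library, so limma p-values of single genes measure only the spread between these libraries.

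Gene lists for B-lineage functions, cell cycle, signalling, metabolism and markers of other marrow cells (27 lists with 508 entries, of which 504 were in the table) were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives not described below as added. Syk is listed as Sykb in the table and was not counted. The 26 lists other than the sex-linked genes were described by their median log2 fold and its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. A list is said to stand apart under percentile 2.5 or over 97.5, and 2 of 100 random lists of 15 genes did so. The same lists were tested in the limma models with camera at a preset correlation of 0.01, adjusted over the 26 lists. At that preset, p-values set the genes of a list against other genes. They do not measure how the list varies between libraries. The alternative with an estimated correlation rests on the 2 residual degrees of freedom, fewer without a library. It could therefore hardly pass a list and decides little either way.

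Named genes follow a rule. Per mutant they are the 12 genes up and 12 down, at least 2-fold in the same direction in both fractions, with the largest value of the smaller fold, and 6 up and 6 down by the same rule for ZnF4 against ZnF1. For C against B they are up to 12 in each direction over the 3 genotypes. Per fraction they are the 5 up and 5 down with the largest fold whose fold in the other fraction is under 1.25-fold or opposite, and up to 5 genes with opposite folds. Ikzf1 to Ikzf5 are always named, and from each list the 2 members with the largest and the 2 with the smallest fold in a comparison may be given as examples. Unnamed transcripts and small RNAs may be given as counts. Some genes that the rule selects are not reported here. Cd72, Irf4, Slc15a2, Ciita, H2-Aa and H2-Eb1, the genes named as shared by both mutants, and list members cited beyond these examples or drawn in a plot were chosen after their values were seen.

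Correlations of log2 folds across genes were computed with scipy 1.17.1 and carry no p-value, since genes are not independent replicates. Within a fraction both mutants are set against the same wt library, so unchanged mutants were simulated against it in 100 sets. Gene names and positions relative to Ikzf1 were looked up in a RefSeq table of assembly GRCm38.p6, to which 9760 of the 10943 genes matched by symbol and 10846 with synonyms. That assembly differs from mm9, so it served for chromosome names and gene order alone. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

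The limma step was tested on simulated data for ZnF4 against wt with 10943 genes and 50 genes changed at each fold. With the spread of all 6 libraries it recovered 14%, 90%, 94% and 98% of genes changed 2, 4, 8 and 16-fold, with 15 false among 163 calls. With the spread of the wt and ZnF4 libraries it recovered 96%, 100%, 100% and 100%, with 21 false among 219 calls. The simulated noise of a gene had the same spread in every library, and each change was the same in both fractions. The real ZnF1 folds differed between fractions, so these shares are no measure of power in the real libraries.

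Alternatives were a pseudocount of 0.25 RPKM, no filter on low values, rescaling by trimmed means of M values (TMM, implemented from the published trims of 30% and 5%), limma without trend, summed transcripts, leaving out each library in turn, fitting only the 4 libraries of the genotypes compared, no genotype term, list means, camera with an estimated correlation, Spearman correlation and a filter of 10 RPKM. Added after the data were seen were leaving out genes of chromosomes X and Y, multiplying the ZnF1 library of fraction C by 1.29 (the factor that brings its B-lineage transcription factor and preBCR genes to the wt level in the median), camera without that library, and the stage comparison in wt and ZnF4 alone. Analyses of binding sites and of the removed exons were not made, because the values per transcript do not resolve exons.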

Results

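RNA of proB cells from the bone marrow of mice aged 6 to 7 weeks was sequenced after sorting into Hardy fraction B and the pooled fractions C and C' (called fraction C), 2 successive stages of early B-lymphocyte development that are told apart by surface markers. The series asks which functions of Ikaros, a zinc finger transcription factor encoded by Ikzf1 and needed for lymphocyte development, rest on individual zinc fingers of its DNA-binding domain. Wild-type mice (wt) were compared with mice mutant in zinc finger 1 (ZnF1 mutant) or zinc finger 4 (ZnF4 mutant). The 6 libraries comprise 1 per genotype and fraction, so a difference between a pair of libraries has no replicate check. The depth is unknown, because the values are RPKM. Between 10342 (ZnF4, fraction B) and 10947 (ZnF1, fraction C) genes reached 1 RPKM per library, and 10943 genes entered the comparisons. By RPKM times transcript length, which stands for reads, the top 10 transcripts held 2.34% to 2.87% of the listed total in 5 libraries and 4.89% in the ZnF1 library of fraction C, where S100a9, a neutrophil calcium-binding protein, alone held 1.07%.

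Ikzf1 itself was at 150.3 RPKM in wt, 181.5 in the ZnF1 mutant and 431.6 in the ZnF4 mutant in fraction B, and at 169.4, 154.1 and 425.1 in fraction C. The ZnF4 libraries were thus 2.86-fold and 2.5-fold above wt, and the limma estimate over both fractions (log2 1.42, SE 0.23) had an adjusted p of 0.117. Values per transcript do not resolve the removed finger, so Ikzf1 does not check the genotype labels. Ikzf3, which encodes Aiolos, the Ikaros relative that rises as B cells mature, stood at 61.9, 11.9 and 282.7 RPKM in fraction B (wt, ZnF1, ZnF4) and at 51.4, 17.4 and 205.4 in fraction C. It was 4.51-fold and 3.94-fold above wt in the ZnF4 libraries, and 4.88-fold and 2.85-fold below wt in the ZnF1 libraries. Ikzf5 was between 3.1 and 5.4 RPKM in every library, Ikzf2 between 0.4 and 1.0, and Ikzf4 at 0.2 or less.

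Sex-linked genes separated the wt libraries from those of both mutants. Xist, the RNA that silences an X chromosome in female cells, was at 81.3 and 91.9 RPKM in wt and listed at 0 in all 4 mutant libraries. The Y-linked genes Eif2s3y (34.4 to 55.1 RPKM), Ddx3y (11.9 to 15), Kdm5d (6.8 to 14.5) and Uty (3.8 to 4.6) were measured in the mutant libraries and listed at 0 in wt. Sex therefore differs with genotype in both comparisons against wt, and not between the mutants.

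**Figure D1:**
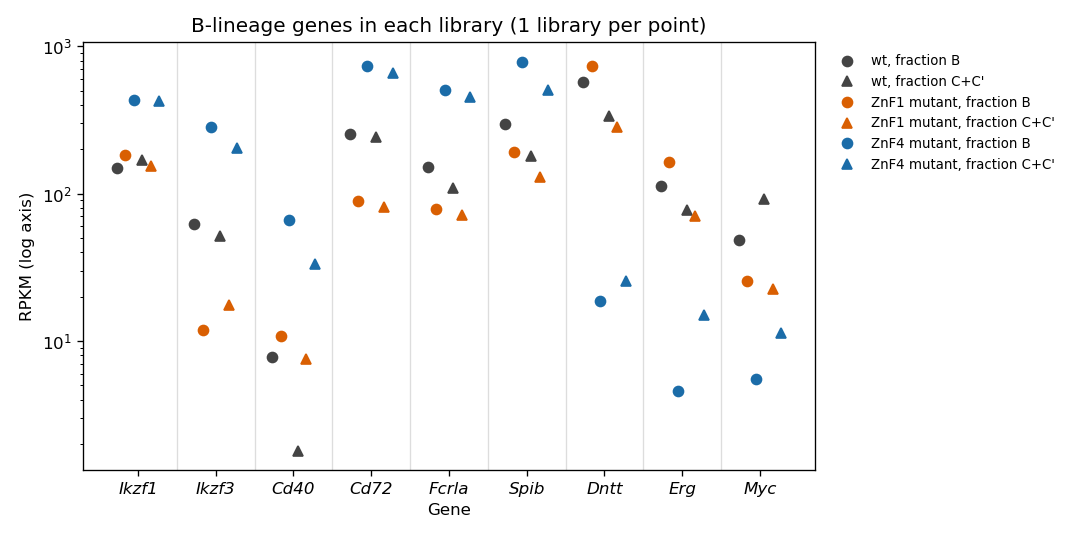
RPKM of 9 B-lineage genes on a log axis, with 1 point per library, circles for fraction B, triangles for fraction C+C', and colours for the genotypes. Ikzf3 runs from 11.9 RPKM in the ZnF1 library of fraction B to 282.7 in the ZnF4 library, and Dntt lies at 18.7 and 25.7 in the ZnF4 libraries against 281.2 to 739.4 in the others.

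The comparison of ZnF4 with wt asks which genes depend on the fourth finger. In both fractions the ZnF4 libraries held more RNA of genes listed for later B-cell stages. They held less of genes of early progenitors, natural killer (NK) cells, glycolysis and DNA replication. The lists for later stages did not rise along the step measured here. From fraction B to C in wt, late preB genes had a median log2 fold of -0.316 and preBCR genes of -0.243. Cd40, a co-stimulatory receptor of maturing B cells, was at 7.8 RPKM in wt and 66.1 in ZnF4 in fraction B and at 1.8 and 33.1 in fraction C (7.62-fold and 12.2-fold higher). Cd74, the invariant chain of MHC class II, was 3.99-fold and 7.01-fold higher. Dntt, the polymerase that adds untemplated nucleotides to V(D)J junctions, was at 568.7 RPKM in wt and 18.7 in ZnF4 in fraction B and at 335.4 and 25.7 in fraction C (28.9-fold and 12.6-fold lower). Myc, a driver of cell growth, was 7.65-fold and 7.54-fold lower, and Erg, a transcription factor of stem and progenitor cells, 20.4-fold and 4.84-fold lower.

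Of 10943 genes, 405 were at least 2-fold higher and 1074 at least 2-fold lower in ZnF4 than in wt in fraction B, and 388 and 670 in fraction C. The same direction in both fractions was seen for 283 higher genes, against 14.36 expected of independent lists, and for 518 lower genes, against 65.757 (780 with a pseudocount of 0.25). Under the fixed rule the highest shared folds outside the Y chromosome included Apba1, a neuronal adaptor protein (9.15-fold and 10.4-fold in fractions B and C), Fam189a1 (11.3 and 8.06), Sema5a, a guidance cue (11.2 and 7.73), Tmtc1 (7.72 and 7.5), Cyp27a1, the sterol 27-hydroxylase (7.57 and 7.11), Gcom1 (7.01 and 10.3) and Cacna1h, a calcium channel subunit (9.92 and 6.91). Frmpd1 was listed at 0 in the wt library of fraction B and stood at 12 RPKM in ZnF4, with 0.1 and 15 in fraction C. The lowest included Camk2b, a calcium-dependent kinase (12.6 RPKM in both wt libraries, 0.1 in both ZnF4 libraries), Myl10 (51.2 and 0.1 in fraction B), Heyl, a Notch target (12.2-fold and 9.88-fold), Scn4b (12.2 and 8.39), Ccdc135 (21.1 and 8.31), Egfl7 (16.6 and 7.91) and Lax1, a lymphocyte adaptor (12.7 and 7.69). Cacna2d1 was at 9.0 and 8.5 RPKM in wt and listed at 0 in both ZnF4 libraries.

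Genes of late preB differentiation were higher in 19 of 20 cases in each fraction, with 11 and 9 of them at least 2-fold higher and a median log2 fold of 1.20 and 0.957. Besides Cd40, Cd74 and Ikzf3 these included Cd72, an inhibitory receptor of B cells (255.9 and 739.4 RPKM in fraction B), and Spib, an Ets factor of B cells (297.3 and 784.5), while Il2ra, the IL-2 receptor alpha chain that marks preB cells, was 1.95-fold and 1.3-fold lower. PreBCR signalling genes had medians of 0.713 and 0.663, with 11 and 12 of 15 higher, among them the adaptors Bank1 (2.21-fold in fraction B) and Pik3ap1 (2.11 and 2.17) and the receptor chain Cd79b (2.05 and 2.48). Mature B-cell genes, with medians of 0.435 and 0.612, went both ways, Faim3 (3.39-fold and 4.69-fold) and Fcrl1 (2.88 and 4.87) being higher, and the chemokine receptor Cxcr5 (3.65 and 4.84) lower. B-lineage transcription factors had medians of 0.225 and 0.25 with 13 and 15 of 21 higher, Erg and Lef1 (3.15-fold and 2.53-fold) being lower. Each of these 4 lists and the Ikaros family (1.52 and 1.32) stood apart from random lists in both fractions. The Ikaros family list held only 3 genes past the filter, and its median is the fold of Ikzf1, the mutated gene. Its member Ikzf3 is also a late preB gene, and Spib and Blk are shared between lists too, so these lists are not independent. Of the recombination genes, Rag2 was 2.38-fold and 1.99-fold lower, Nhej1 2.05-fold higher in fraction B, and the list did not stand apart (-0.262 and -0.232).

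On the low side, NK and cytotoxic genes had medians of -2.58 and -1.79, with 0 of 11 higher. The chemokine Ccl5 was at 28.0 RPKM in wt and listed at 0 in ZnF4 in fraction B, and at 12.3 and 1.2 in fraction C. The granzyme Gzma was at 17.0 and 0, then 8.1 and 0.4. Plasmacytoid dendritic genes (-2.04 and -1.0) included the lectin Siglech (22.9-fold and 7.73-fold lower) and Runx2 (8.3 and 0.1 RPKM in fraction B), while the nucleic acid receptor Tlr9 was 3.59-fold and 4.11-fold higher. Myeloid (-1.74 and -0.484) and erythroid markers (-1.30 and -0.515) were also low, with Fcer1g, an immune receptor chain, 11-fold and 3.23-fold and the red cell anion exchanger Slc4a1 5.98-fold and 2.57-fold lower. Progenitor genes (-0.926 and -0.469) included the cytokine receptor Flt3 (10.1 and 0.4 RPKM in fraction B), while the IL-7 receptor chain Il7r was 2.86-fold and 2.97-fold higher. Glycolysis genes (-0.907 and -0.837; 0 and 1 of 13 higher) included Ldha, the lactate dehydrogenase subunit (3.2-fold and 2.75-fold lower), and the hexokinase Hk2 (2.9-fold lower in both fractions), with the glucose transporter Slc2a1 within 1.05-fold of wt.

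DNA replication genes had medians of -0.838 and -0.344, with 1 and 2 of 30 higher, and Ccne2, the cyclin that starts S phase, was 3.34-fold and 2.08-fold lower. Mitosis genes were low in fraction B (-0.636; 0 of 30 higher) and high in fraction C (0.17; 25 of 30 higher). Interferon response genes (-0.885 and -0.6; Irf7 5.84-fold and 2.85-fold lower), integrin and adhesion genes (-0.862 and -0.277; Itgb7 8.33-fold lower in fraction B), T-lineage and Notch genes (-0.758 and -0.52; Cd7 16.3-fold and 5.18-fold lower), IL-7 and STAT5 response genes (-0.595 and -0.377) and immediate early genes (-0.692 and -0.447; Fosb 3.17-fold and 2.69-fold lower) stood apart as low in both fractions. Within the IL-7 and STAT5 list the GTPase Gimap4 was 16.6-fold and 2.87-fold lower and the survival kinase Pim2 2.53-fold and 2.6-fold higher. Hardy sort markers (-0.711 and -0.011) and stroma (-0.926 and -0.536) stood apart as low in fraction B, and ribosomal proteins (-0.268 and -0.317) in fraction C. Glucose restraint genes (0.227 and 0.086), p53 targets (-0.073 and -0.021), histones (0.0 and 0.354) and megakaryocyte genes (-0.505 and -0.041) did not stand apart in either fraction.

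**Figure D2:**
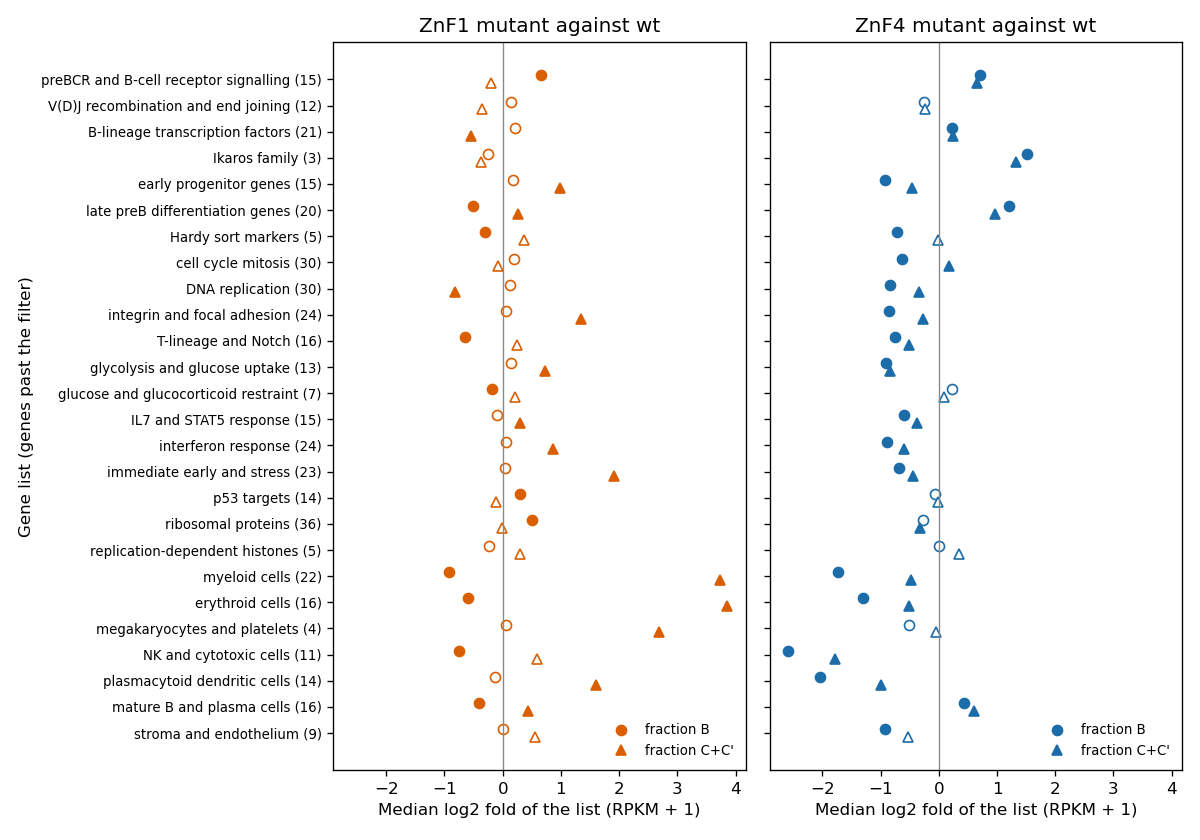
Median log2 fold against wt of 26 gene lists in each fraction, circles for fraction B and triangles for fraction C+C', filled where the list stands apart from random lists of the same size. In the ZnF4 panel NK genes lie at -2.58 and -1.79, and in the ZnF1 panel myeloid genes lie at -0.914 in fraction B and 3.74 in fraction C.

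Fitted over all 6 libraries, limma called 3 genes for ZnF4 against wt, each of them sex-linked: Eif2s3y rose (log2 5.79, adjusted p = 0.0138) and Xist and Tsix fell (adjusted p = 0.0138 and 0.0301), in 2 of 2 fractions, while 1930 genes had an unadjusted p under 0.05. Without the filter on low values 0 passed (2426 at an unadjusted p under 0.05). Adjusted over the list alone, 10 of 20 late preB genes passed as higher, 9 of 11 NK genes and 6 of 13 glycolysis genes as lower, against 0 over all genes for each of these lists. In camera 9 of 26 lists passed, late preB (adjusted p = 5.88e-09), preBCR (0.00652), Ikaros family (0.0107) and mature B genes (0.0373) as higher and NK (5.13e-08), glycolysis (3.86e-05), interferon (0.000237), replication (0.000636) and plasmacytoid dendritic genes (0.00201) as lower. With an estimated correlation none of the 26 passed, with adjusted p = 0.843 for late preB genes, glycolysis and the Ikaros family and adjusted p = 0.855 for the other 6. Without the ZnF1 library of fraction C these 9 lists passed again, and myeloid (0.000249) and erythroid genes (0.000901) passed as lower, with adjusted p = 0.788 as the smallest with an estimated correlation.

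The number of limma calls rested on single libraries. It was 3494 in the 4 libraries of wt and ZnF4 alone, 3453 (1339 higher, 2114 lower) without the ZnF1 library of fraction C and 3372 without that of fraction B, since either omission leaves the other ZnF1 library, assumed to vary like the other groups, out of the spread. It was 0 without any one of the wt or ZnF4 libraries, with 717 (wt, fraction B), 493 (ZnF4, fraction B), 798 (wt, fraction C) and 777 (ZnF4, fraction C) genes at an unadjusted p under 0.05 in limma. Without the ZnF1 library of fraction C the changes of Dntt (log2 -4.26, SE 0.29, adjusted p = 0.00525), Cd40 (3.27, SE 0.19, 0.00482), Myc (-2.92, SE 0.1, 0.00385), Ikzf3 (2.08, SE 0.1, 0.00482), Ikzf1 (1.42, SE 0.12, 0.0057) and Ldha (-1.57, SE 0.11, 0.00507) passed, and with all 6 libraries Dntt, Cd40 and Myc had an adjusted p of 0.0896 each. Over the 14 alternatives in limma the adjusted p of these genes ran from 0.00322 (Myc) to 0.953 for Dntt, Cd40, Myc and Ikzf3 and to 1 for Ikzf1 and Ldha.

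The comparison of ZnF1 with wt asks which genes depend on the first finger. In both fractions the ZnF1 libraries held less RNA of Ikzf3, of Cd72 (2.86-fold and 2.98-fold lower) and of Emid1 (14.6 and 2.0 RPKM in fraction B, 7.78-fold lower in fraction C), and more of Gimap4 (5.65-fold and 3.44-fold) and Gimap3 (4.88 and 4.27), a pair of lymphocyte GTPases. Fgd2, an exchange factor for Cdc42, was at 11.1 RPKM in wt and 60.3 in ZnF1 in fraction B and at 5.5 and 32.3 in fraction C. The fractions otherwise differed. The fraction C library of the ZnF1 mutant held far more RNA of genes of granulocytes, monocytes and red cells than that of wt, which its fraction B library did not.

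In fraction B 226 genes were at least 2-fold higher and 242 at least 2-fold lower than wt, and in fraction C 1379 and 809. With a pseudocount of 0.25 the lower genes in fraction B were 402, and after rescaling on B-lineage genes those in fraction C were 375. The same direction in both was seen for 83 higher genes (28.48 expected of independent lists) and 88 lower ones (17.891). The higher ones included the cytokine receptor Il9r (8.18-fold and 5.18-fold), the mucin Muc13 (6.58 and 4.59), the scavenger receptor Cd36 (4.16 and 5.05) and Rnase12 (4.97 and 4.12). The lower ones included Camk2b, listed at 0 in both ZnF1 libraries, the RNA-binding protein Khdrbs3 (5.75 and 8.75), the cardiac troponin Tnnt2 (5.36 and 8.08), Ttll11 (5.33 and 7.83), Rsph1 (5.16 and 6.07), Rbpms (5.6 and 4.97), the lipid phosphatase Inppl1 (4.5 and 6.9), Tmprss3 (4.31 and 6.8) and Egfl6 (4.81 and 4.24). Genes at least 2-fold apart in fraction B, and close to wt or opposite in fraction C, included Id3, an inhibitor of E proteins (31.4 RPKM in wt and 135.7 in ZnF1), the transcription factor Maf (3.26-fold higher), and on the low side the adhesion molecule Cd2 (38.1 and 4.4), the polymerase Polm (45.6 and 7.3) and Adam19 (30.2 and 5.1, but 9.0 and 17.5 in fraction C).

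In fraction B the preBCR list was high (0.653; 14 of 15 genes higher), with Bank1 2.82-fold and Vpreb2, a surrogate light chain, 2.38-fold higher and the kinase Blk 1.95-fold lower. Ribosomal proteins (0.506; 30 of 36 higher) and p53 targets (0.296) were also high. Late preB genes were low (-0.512), led by Cd2 and Ikzf3, although Ltb was 3.2-fold higher. T-lineage genes (-0.649; Lat 3.89-fold and Thy1 2.62-fold lower), mature B genes (-0.404), Hardy sort markers (-0.3), myeloid (-0.914), erythroid (-0.602) and NK markers (-0.749) were low, as was the glucose restraint list by its median (-0.191) though not by its mean (0.184). The remaining lists did not stand apart: recombination (0.142), B-lineage transcription factors (0.209), the Ikaros family (-0.253), progenitors (0.175, with Flt3 2.75-fold and the stem cell antigen Ly6a 2.44-fold higher), mitosis (0.202), replication (0.119), integrins (0.055), glycolysis (0.138), IL-7 response (-0.091), interferon (0.063), immediate early (0.048), histones (-0.241), megakaryocytes (0.055), plasmacytoid dendritic cells (-0.128) and stroma (0.0).

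In fraction C all 22 myeloid genes were at least 2-fold higher in the ZnF1 library (median 13.3-fold), as were 15 of 16 erythroid genes (median 14.5-fold). S100a9 was at 870.3 RPKM in wt and 18584.6 in ZnF1, the siderophore-binding protein Lcn2 at 139.6 and 3126.6, myeloperoxidase (Mpo) at 44.8 and 564.5, the globin Hbb-b1 at 103.4 and 2078.6 and Slc4a1 at 35.8 and 530.1. The cytokine Il1b was at 5.5 and 251.6 RPKM, and Mcpt8, Fpr2 and Il1r2, genes of basophils and neutrophils, were 27.4-fold, 26.7-fold and 26.5-fold higher. Megakaryocyte (2.68), immediate early (1.90), plasmacytoid dendritic (1.60), integrin (1.34), progenitor (0.984), interferon (0.86), glycolysis (0.724), mature B (0.432), IL-7 response (0.303) and late preB lists (0.269) were high beside them in the same library. Their examples included Ier3 (22.1-fold), Ly6c2 (21.0), Actn1 (12.5), Tal1 (11.7), Rsad2 (10.5) and, among late preB genes, Cd74 (5.0-fold) and H2-Eb1 (4.09), with Cd22 4.98-fold lower.

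In that library B-lineage transcription factors were low (-0.545; 2 of 21 higher), the B-cell factor Pax5 being 2.45-fold and Mef2c 2.46-fold lower and the myeloid and B-cell factor Sfpi1 3.8-fold higher. Replication genes were low as well (-0.826; 1 of 30 higher), with Gins1 2.32-fold lower. RPKM are relative to the library, so a larger share of myeloid and erythroid RNA would also lower these values. The median of all genes was -0.159, and 0.169 after multiplying this library by 1.29. That factor was set on B-lineage genes, so it cannot tell whether their expression per cell fell. The preBCR (-0.207), recombination (-0.352), Ikaros (-0.37), Hardy marker (0.364), mitosis (-0.089), T-lineage (0.241), glucose restraint (0.219), p53 (-0.122), ribosomal (-0.009), histone (0.29), NK (0.585) and stroma lists (0.55) did not stand apart. At least 2-fold differences in opposite directions were seen for 85 genes lower in fraction B and higher in fraction C (30.496 expected), among them Fos (25.6 and 5.4 RPKM in fraction B, 16.2 and 201.6 in fraction C) and the granule protein Ngp (662.5 and 189.3, then 487.4 and 5458.0), and for 6 genes the other way (16.708 expected).

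**Figure D3:**
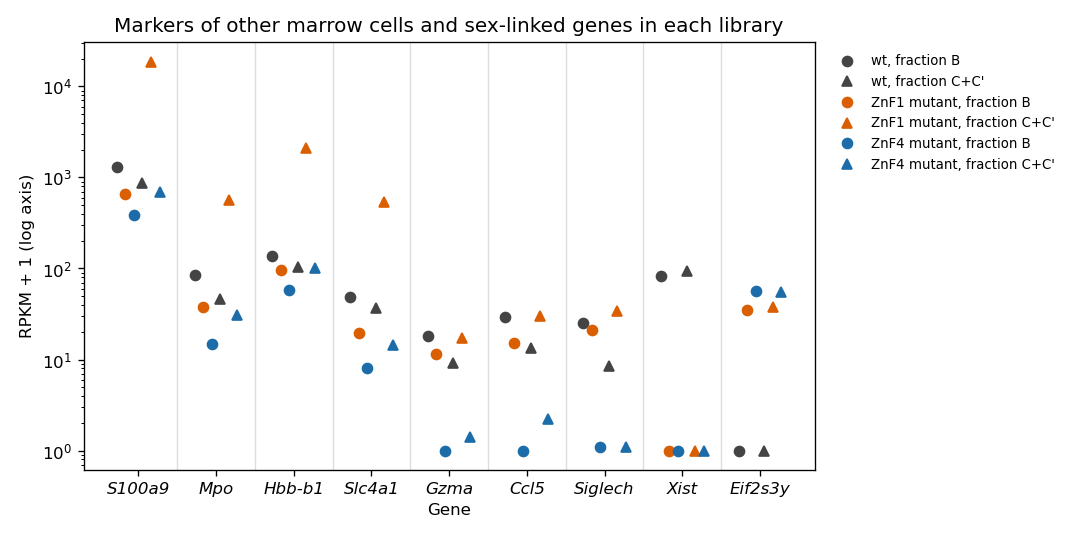
RPKM + 1 of markers of other marrow cells and of sex-linked genes on a log axis, with 1 point per library, circles for fraction B and triangles for fraction C+C'. S100a9, Mpo, Hbb-b1 and Slc4a1 are highest in the ZnF1 library of fraction C (18584.6, 564.5, 2078.6 and 530.1 RPKM), while Gzma and Siglech are lowest in the ZnF4 libraries.

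Over all 6 libraries limma called 3 genes for ZnF1 against wt, again Eif2s3y (rose by log2 5.19, adjusted p = 0.0138), Xist (fell by 6.45, adjusted p = 0.0138) and Tsix (fell, adjusted p = 0.0338), in 2 of 2 fractions, with 1018 genes at an unadjusted p under 0.05. Without the filter on low values 0 passed (1305 at an unadjusted p under 0.05), as in the 4 libraries of wt and ZnF1 alone (453). Adjusted over the list alone, 3 late preB and 3 T-lineage genes passed as lower and 1 late preB and 2 mature B genes as higher, against 0 over all genes. In camera 9 lists passed as higher: immediate early (adjusted p = 6.46e-05), interferon (0.000214), myeloid (0.000685), erythroid (0.00139), progenitor (0.00143), plasmacytoid dendritic (0.00143), integrin (0.00228), ribosomal (0.0231) and megakaryocyte genes (0.0348). With an estimated correlation the adjusted p = 0.963 for myeloid, erythroid and ribosomal genes and adjusted p = 0.9 for the others. The myeloid and erythroid lists passed as higher although their medians in fraction B were negative. Without the ZnF1 library of fraction C they passed as lower (0.000617 and 0.00619), as did late preB (0.00321) and T-lineage genes (0.006), while ribosomal (0.0003), preBCR (0.000617), mitosis (0.006) and replication genes (0.0158) passed as higher and immediate early, interferon, progenitor, plasmacytoid dendritic, integrin and megakaryocyte genes did not pass, with adjusted p = 0.971 as the smallest with an estimated correlation. The number of limma calls was 4116 without the ZnF1 library of fraction B, which sets that of fraction C alone against wt, and 16 without that of fraction C. It was 0 without any other library, with 738 (wt) and 452 (ZnF4) genes at an unadjusted p under 0.05 without the fraction B library and 162 and 450 without that of fraction C.

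The direct comparison of the mutants asks whether the fingers act on different genes, and it does not use the wt libraries as a reference. Srpk3, a muscle serine/arginine kinase, was at 2.1 RPKM in ZnF1 and 69.8 in ZnF4 in fraction B and at 1.4 and 49.2 in fraction C (limma log2 4.45, SE 0.17, adjusted p = 0.0359). Ikzf3 (log2 3.97, SE 0.29, adjusted p = 0.0359), Cd72 (3.03, 0.0359), the Fc receptor-like gene Fcrla (2.66, 0.036), Bach2, a repressor of plasma cell fate (2.23, 0.0377), Spib (1.99, 0.0413) and Irf4 (1.77, 0.0487) also rose from ZnF1 to ZnF4. Dntt (-4.32, 0.0413), Siglech (-4.61, 0.0487), Gimap3 (0.0377), Fgd2 (-2.07, 0.0377) and Muc13 (0.0359) fell. Each lay in the same direction in 2 of 2 fractions, for instance Siglech at 20.2 RPKM in ZnF1 and 0.1 in ZnF4 in fraction B and at 33.0 and 0.1 in fraction C.

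At least 2-fold differences in both fractions were seen for 340 genes higher in ZnF4 (40.168 expected) and 596 lower (169.045). Further genes named by the rule were Tmprss3 (16.7-fold and 17.3-fold), Egfl6 (15.9 and 16.4), Rsph1 (19.2 and 14.7), the matrix protease Mmp14 (14.2 and 15) and Myl4 (14.1 and 19.8) on the high side, and Dok2 (14.5 and 19.8), Cd209d and Ccl5 on the low side. Dok2 (0.0377) and Cd209d (0.0491) passed, and Ccl5 had an adjusted p of 0.0647. Late preB genes (medians 1.53 and 0.615) and the Ikaros family (1.24 and 1.46) were high in both fractions. NK (-2.35 and -2.23), plasmacytoid dendritic (-1.68 and -2.69), interferon (-1.04 and -1.38), glycolysis (-0.926 and -1.28), myeloid (-0.753 and -4.31) and erythroid genes (-0.78 and -4.71) were low. B-lineage transcription factors had medians of 0.016 and 0.663, and a mean of -0.157 in fraction B. Adjusted over the list alone, 10 late preB genes passed as higher and 1 as lower, and 11 NK, 15 interferon and 9 glycolysis genes as lower. Over all genes 4 late preB genes passed as higher and 1 as lower, and 2 NK, 2 interferon and 1 glycolysis genes as lower.

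limma called 125 genes as higher and 74 as lower in ZnF4 than in ZnF1, with 2489 at an unadjusted p under 0.05. The excess of higher calls held with TMM (182 and 159) and with a pseudocount of 0.25 (144 and 124). After rescaling the ZnF1 library of fraction C, limma called 118 as higher and 162 as lower, and in the 4 libraries of the mutants alone 70 and 81. It called 4109 without the ZnF1 library of fraction B, 2689 without that of fraction C and 0 without either ZnF4 library (922 and 993 at an unadjusted p under 0.05 without that of fraction B and C). Without the filter on low values, over 15655 genes, 0 passed (smallest adjusted p = 0.0871, 3025 at an unadjusted p under 0.05), so that each call named here ended, and TMM gave 341. In camera 12 lists passed, late preB genes (adjusted p = 7.5e-07) and the Ikaros family (0.0025) as higher and 10 as lower, among them interferon (1.22e-07), NK (7.5e-07), glycolysis (3.33e-05), myeloid (3.44e-05), plasmacytoid dendritic (4.36e-05), erythroid (0.000331) and integrin genes (0.000931). All 12 had an adjusted p = 0.655 with an estimated correlation. Replication genes (medians -0.954 and 0.423) and mitosis genes (-0.804 and 0.273) went opposite ways in fractions B and C and did not pass over all 6 libraries. The fit that follows holds only the fraction B library of ZnF1, where both lists were lower in ZnF4. Without the ZnF1 library of fraction C myeloid (adjusted p = 0.216), erythroid, integrin and progenitor (0.149 each) and immediate early genes (0.913) no longer passed, while replication (5.8e-06), mitosis (0.00401) and mature B genes (0.00401, higher) did, with adjusted p = 0.924 as the smallest with an estimated correlation.

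Among genes at least 2-fold from wt in both fractions, 21 were lower in ZnF1 and higher in ZnF4 (2.276 expected of independent lists), among them Ikzf3, Cd72, Srpk3, Myl4, Mmp14 and Rsph1. A further 10 were higher in ZnF1 and lower in ZnF4 (3.929 expected), with Gimap3, Gimap4, Dok2 and Muc13. The 27 genes lower in both mutants (4.166 expected) included Camk2b, Cacna2d1, Xist and the matrix genes Col1a1, Col1a2 and Sparc. They also held Ptma, Hmgb2, Cbx3, microRNAs and small nucleolar RNAs, whose values are uncertain, and Tsix, which cannot be told apart from Xist. The excess rests in part on these. The 7 higher in both (2.146 expected) were Cyp27a1, the inhibitory Fc receptor Fcgr2b, Slc15a2 and the Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty. Simulated unchanged mutants against the same wt libraries gave 0 such genes in 100 sets, because their spread is too small to reach these thresholds, so the simulation gives no measure of the excess, and part of any excess may come from the shared wt libraries.

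The comparison of fraction C with fraction B follows the step within the proB stage. In wt, cell cycle genes were higher and myeloid, erythroid, NK and plasmacytoid dendritic genes lower in fraction C, with all 30 replication genes (median 0.513) and all 30 mitosis genes (0.348) higher. Enpep, the aminopeptidase BP-1 whose surface display separates these fractions in the Hardy scheme, was at 3.5 RPKM in B and 56.6 in C in wt, 2.3 and 20.2 in ZnF1 and 1.1 and 43.1 in ZnF4. The progenitor genes Ly6d and Flt3 were 4.92-fold and 4.11-fold lower in fraction C in wt, and the recombinase gene Rag1 2.36-fold lower.

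In wt 37 genes were at least 2-fold higher and 111 lower in fraction C, in ZnF4 302 and 64, and in ZnF1 1101 and 455. With TMM scaling the counts were 151 and 104 in ZnF4, and 274 genes were lower in ZnF1, or 153 after rescaling that fraction C library. With a pseudocount of 0.25 they were 77 and 208 in wt and 524 and 119 in ZnF4, with 685 lower in ZnF1. All 3 genotypes shared 3 higher genes (0.103 expected), namely Enpep, the metallothionein Mt1 and a small nucleolar RNA, and 3 lower ones (0.027 expected), namely Col5a3, growth hormone (Gh) and a microRNA, against 5 and 9 with a pseudocount of 0.25 and 6 lower ones with TMM. Ribosomal (0.398) and glycolysis genes (0.462) were high in wt. Plasmacytoid dendritic (-1.06), NK (-0.773), myeloid (-0.527), erythroid (-0.347), progenitor (-0.434), interferon (-0.426), mature B (-0.403), late preB (-0.316; Cd2 3.87-fold and Il2ra 3.45-fold lower), recombination (-0.286) and preBCR genes (-0.243) were low. In ZnF4 mitosis (1.16; 28 of 30 genes at least 2-fold higher) and replication genes (0.963) were high, beside myeloid (0.747; 20 of 22 higher), erythroid (0.489; 14 of 16) and NK genes (0.379). In ZnF1 mitosis genes were high (0.121), and replication genes were low (-0.352; 1 of 30 higher), a direction that turned to 0.002 when that fraction C library was rescaled on its B-lineage genes. PreBCR genes (-1.01) and B-lineage transcription factors (-0.868) were low in ZnF1, beside myeloid (4.08) and erythroid genes (4.31), which were high. The median of all genes was -0.158 there, and a larger share of other RNA cannot be told apart from lower expression.

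limma called 0 genes for fraction C against B, with 511 at an unadjusted p under 0.05, and Enpep (log2 3.59, SE 0.36, higher in 3 of 3 genotypes) had an adjusted p of 0.854. In camera mitosis (adjusted p = 1.3e-11), glycolysis (1.3e-06), replication (5.93e-06), myeloid (8.02e-06), erythroid (6.74e-05), integrin genes (0.00802) and Hardy markers (0.0191) passed as higher, each with adjusted p = 0.659 with an estimated correlation. The medians of myeloid, erythroid and integrin genes and Hardy markers were negative in wt. PreBCR (1.81e-05), B-lineage transcription factors (2.33e-05), late preB (0.000213), recombination (0.00136), mature B (0.0014) and glucose restraint genes (0.0176) passed as lower, again with adjusted p = 0.659 with an estimated correlation. Without the ZnF1 library of fraction C replication (5.21e-13), mitosis (3.9e-09) and late preB genes (3.47e-08) passed in the same directions, with adjusted p = 0.734 as the smallest with an estimated correlation, and myeloid, erythroid, integrin and recombination genes and Hardy markers no longer passed.

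Across the 10943 genes, which are not independent replicates, the ZnF4 folds in fractions B and C, which share no library, correlated at r = 0.841 (Spearman 0.812) with the same sign for 80.5% of genes. The ZnF1 folds correlated at 0.052 (Spearman 0.168), with the same sign for 52.5%. Whether both fractions of a genotype came from the same animals is not known here, and sex differed from wt in both. Agreement between fractions, in these correlations or in the counts of shared genes, is therefore no replication of a genotype effect. Within a fraction the folds of ZnF1 and ZnF4, which share the wt library, correlated at 0.132 in B and 0.064 in C. Simulated unchanged mutants gave 0.5, a value fixed by the equal spread of every simulated library, so it is no measure for these folds. The covariances of the real folds, 0.044 and 0.0408, lay 0.0026 above and 0.0006 below the simulated 0.0414. The simulated spread was taken from how wt and ZnF4 differ between fractions, so it includes any such effect of ZnF4. Pairs that share no library correlated at 0.113 (ZnF1 in B with ZnF4 in C) and at -0.175 (ZnF1 in C with ZnF4 in B, Spearman 0.029). The step from B to C correlated at 0.465 between wt and ZnF4, at -0.273 between wt and ZnF1 and at 0.088 between the mutants. These 9 correlations form 1 family and carry no p-value.

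**Figure D4:**
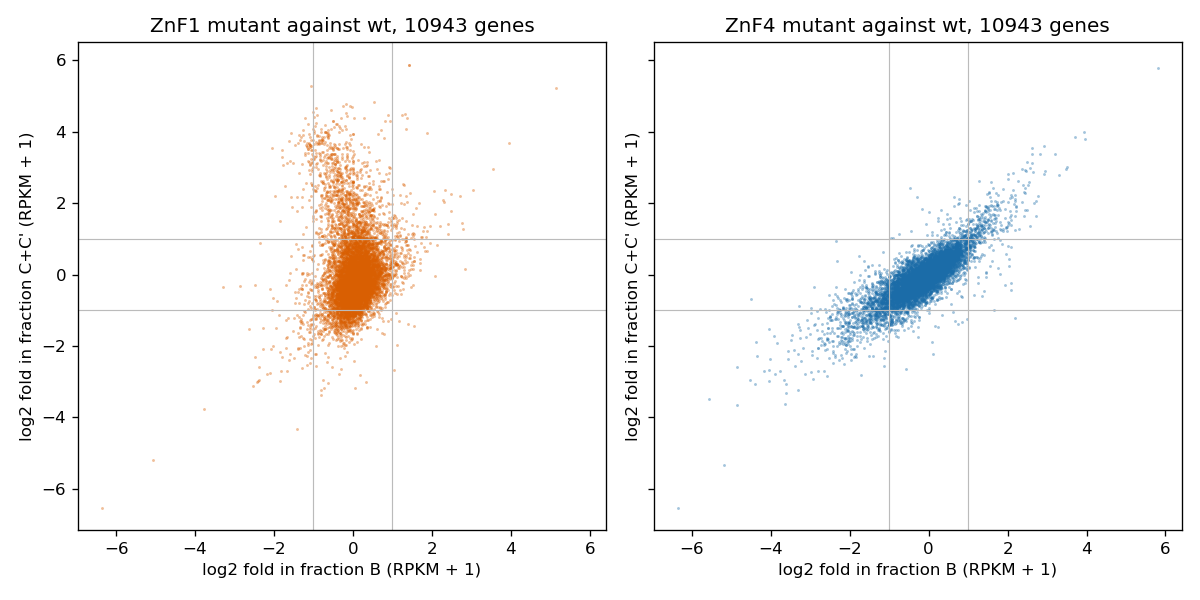
Log2 fold against wt in fraction B (horizontal) and fraction C+C' (vertical) for 10943 genes, 1 point per gene, with lines at 2-fold. The ZnF4 points follow the diagonal (r = 0.841), and the ZnF1 points do not (r = 0.052), with 85 genes lower in fraction B and higher in fraction C.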

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

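The tests of where the RNA of myeloid, erythroid, NK and plasmacytoid dendritic genes came from were chosen only after these results were seen. The results here are differences between the effects in both fractions or in different genotypes that went in opposite directions, for lists that stood apart from random lists both times and for named genes. With 1 library per group, none of these differences was tested.

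Against wt, the ZnF1 mutant showed opposite medians for 4 lists that stood apart in both fractions. Myeloid genes went from -0.914 to 3.74 (difference 4.65, log2), erythroid genes from -0.602 to 3.85 (4.46), mature B genes from -0.404 to 0.432 (0.836) and late preB genes from -0.512 to 0.269 (0.781). Single genes did the same: Fos (5.61), Prg3, an eosinophil granule protein (4.17), Ngp (5.28), Thbs1 (5.09) and Slfn4 (4.83). In the ZnF4 mutant mitosis genes went from -0.636 to 0.17 (0.806). Among small RNAs Snord68 (difference -3.43) and Mir466i (-2.64) were higher in fraction B and lower in fraction C in that mutant.

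The step from fraction B to C had opposite medians in ZnF1 and wt for 9 lists that stood apart in both. The difference, ZnF1 minus wt, was 4.61 for myeloid, 4.66 for erythroid, 2.33 for immediate early, 1.78 for plasmacytoid dendritic, 1.08 for integrin, 1.05 for T-lineage, 0.768 for interferon, 0.394 for late preB and -0.865 for replication genes, whose median in ZnF1 turned to 0.002 after rescaling its fraction C library. For ZnF4 minus wt it was 1.27 for myeloid, 0.836 for erythroid and 1.15 for NK genes.

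Myeloid and erythroid genes were higher in the ZnF1 library of fraction C alone, with S100a9 at 18584.6, S100a8 at 8493.0 and Hbb-b1 at 2078.6 RPKM. The myeloid median was -0.914 in fraction B, where a mutation that raises these genes in both fractions would raise it. That value is part of the flagged pattern and no separate test. A loss of B-lineage cells that raises all other cell types alike would bring the NK median near the myeloid one. In this library the NK median lay -3.15 from the myeloid one (SD 0.38), so NK and myeloid genes did not rise alike there. With 1 library this difference cannot decide whether such a loss occurred. The SDs here are those of random gene lists, not of libraries. The sex of the animals is argued against by the ZnF4 library, which shares the sex-linked profile of ZnF1 and lay -4.71 (erythroid, SD 0.186) and -4.31 (myeloid) from it in fraction C. RNA of myeloid and erythroid cells in that library remains a candidate source, with 37 of the 38 members at least 2-fold higher, but an effect of the ZnF1 mutation in fraction C alone, or on which cells enter that gate, cannot be told apart from it with 1 library. Sorting for Hardy fractions would be expected to remove such cells, although 20 of 22 myeloid and 16 of 16 erythroid members reached 1 RPKM in both wt libraries, and 0 of them are on another list.

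NK and plasmacytoid dendritic genes were lower in both ZnF4 libraries. Their wt levels in fraction B were 28.0 RPKM for Ccl5, 17.0 for Gzma and 70.3 for Bst2. The NK median lay -1.28 from the erythroid one (SD 0.301) in fraction B. The SDs here are those of random gene lists, not of libraries. This difference cannot decide whether RNA of all other cell types fell alike. Ccl5 and Gzma were listed at 0 in ZnF4 in fraction B, and each group has 1 library. The sex of the animals is argued against as the sole source by the mutants, which share their sex-linked profile: the NK median of ZnF4 against ZnF1 was -2.35 in fraction B and -2.23 in fraction C (SD 0.39), and the plasmacytoid dendritic one -1.68 and -2.69. Rounding of low values is argued against by the 4 NK members with a mean of at least 5 RPKM, whose median was -2.65 in fraction C. The 11 NK members all reached 1 RPKM in both wt libraries, as did 13 of 14 plasmacytoid dendritic members, of which 2 are on another list. Whether the sort removes these cell types was not tested. Fewer NK and dendritic cells in the sorted fractions, less RNA of all other cell types alike and lower expression of these genes in the proB cells stay open.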

How the results depend on the processing

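Leaving out X and Y genes, rescaling the ZnF1 library of fraction C, camera without that library and the stage comparison in wt and ZnF4 alone were chosen only after the results were seen. Depth is unknown, so no limit from counting error can be given, and each group has 1 library. No paired analysis of replicates was possible because each genotype and fraction has 1 library. The limma models compare genotypes within fractions and fractions within genotypes.

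Of 26 counts of genes at least 2-fold apart, 26 stayed within 1.5 times without the filter on low values and 26 without X and Y genes. The number was 17 with a pseudocount of 0.25, 22 with TMM and 23 after rescaling. Rescaling changes only counts that use the ZnF1 library of fraction C, so the other counts stayed by construction. With the pseudocount of 0.25 the exceptions were 402 lower genes for ZnF1 in fraction B, 780 shared lower genes for ZnF4, and for C against B 77 higher and 208 lower in wt, 685 lower in ZnF1, 524 and 119 in ZnF4, and 5 and 9 in all genotypes. With TMM they were 274 lower genes for C against B in ZnF1, 151 higher and 104 lower in ZnF4, and 6 lower in all genotypes. After rescaling they were 375 lower genes for ZnF1 in fraction C, 470 higher genes for ZnF4 against ZnF1 in fraction C and 153 lower genes for C against B in ZnF1. In wt and ZnF4 alone 8 higher and 20 lower genes were shared for C against B, a comparison over fewer genotypes.

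TMM moved the median of all genes by over 0.1 (log2) for ZnF1 in fraction C (0.133), ZnF4 in fraction B (0.101), ZnF4 against ZnF1 (0.148 and -0.117) and C against B in ZnF1 (0.128) and ZnF4 (-0.133), and rescaling moved it by 0.327 for ZnF1 in fraction C, by -0.33 for ZnF4 against ZnF1 and by 0.327 (from -0.158 to 0.169) for C against B in ZnF1. The share of higher genes moved from 63.0% to 73.8% (TMM) and 83.7% (rescaled) for ZnF1 in fraction C, from 48.5% to 58.8% (rescaled) for genes shared by both ZnF1 fractions, from 31.2% to 43.8% (TMM) and from 34.4% to 18.8% (rescaled) for ZnF4 against ZnF1 in fractions B and C. For C against B it moved from 70.8% to 81.9% and 90.8% in ZnF1, from 82.5% to 59.2% (TMM) in ZnF4, and from 50% to 35.7% (pseudocount 0.25) and 33.3% (TMM) for genes shared by all genotypes.

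In limma, 0 genes passed without the filter for ZnF1 (1305 at an unadjusted p under 0.05), ZnF4 (2426) and ZnF4 against ZnF1 (3025), and 0 without X and Y genes for ZnF1 (983) and ZnF4 (1873), where the sex-linked calls are left out by construction. Without trend 5 genes passed for ZnF1 and 6 for ZnF4. For ZnF4 5 passed with the pseudocount of 0.25 and 5 with TMM, and TMM gave 341 for ZnF4 against ZnF1. In the 4 libraries of the compared genotypes 0 passed for ZnF1 (453 at an unadjusted p under 0.05) and 3494 for ZnF4. Leaving out 1 library in turn gave 0 to 4116 calls for ZnF1, 0 to 3453 for ZnF4, 0 to 4109 for ZnF4 against ZnF1 and 0 for C against B, the lone library of a genotype being assumed to vary like the others. In camera 0 of 26 lists passed with an estimated correlation in each of the 4 comparisons, with and without the ZnF1 library of fraction C. At the preset correlation 4 higher and 4 lower lists passed without that library for ZnF1, 4 and 7 for ZnF4, 3 and 7 for ZnF4 against ZnF1 and 4 and 9 for C against B.

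Of 234 list medians, 189 stayed within the spread of random lists with the pseudocount of 0.25, 198 without the filter and 196 with TMM. The number was 170 after rescaling and 168 as means. Rescaling changes only comparisons that use the ZnF1 library of fraction C, so the medians of the others stayed by construction. Among those that could change, 63 moved by more than that spread and 1 turned. The direction turned for 3: B-lineage transcription factors for ZnF4 against ZnF1 in fraction B (-0.157 as a mean), glucose restraint genes for ZnF1 in fraction B (0.184 as a mean) and replication genes for C against B in ZnF1 (0.002 after rescaling). Of 400 folds of named genes, 132 moved by more than the gene's residual SD in limma with the pseudocount of 0.25, and 0 with TMM. Leaving out the filter cannot change the fold of a gene, so the 0 moved folds there hold by construction. None of these settings turned a fold of at least 2. By Spearman the correlation was 0.168 for ZnF1 across fractions, 0.812 for ZnF4, 0.198 for both mutants in fraction C and 0.029 for ZnF1 in C with ZnF4 in B, which is negative by Pearson. Among genes of at least 10 RPKM it was 0.862 for ZnF4 across fractions, 0.093 and 0.089 for both mutants in fractions B and C and 0.076 for ZnF1 in B with ZnF4 in C. Where no construction is named, the cause was not tested.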

Other observations

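The tests of genes shared by both mutants and the reading of the sample splits were chosen only after the results were seen.

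The values of 3 genes of antigen presentation were singled out after they were seen, and no group was tested. Ciita, the transactivator of MHC class II genes, was at 4.5 RPKM in wt and 13.7 in ZnF4 in fraction B and at 4.0 and 13.6 in fraction C, against 4.3 and 5.0 in the ZnF1 libraries. H2-Aa, an MHC class II chain, was at 56.2 and 175.6 RPKM in wt and ZnF4 in fraction B and at 33.0 and 182.4 in fraction C, and H2-Eb1 at 20.7 and 48.9, then 10.9 and 42.1. In the ZnF1 library of fraction C, beside its myeloid and erythroid RNA, H2-Aa was at 131.1 RPKM and H2-Eb1 at 47.7. A few named genes differed in 1 fraction of the ZnF4 mutant: Ly6d, a marker of B-lineage specification, was at 46.7 RPKM in wt and 143.4 in ZnF4 in fraction C, and at 233.7 and 277.4 in fraction B, whereas Thy1 (12.6 and 2.5) and the cyclin Ccnd1 (6.1 and 0.9) were lower in fraction B alone.

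Overlaps between the mutants were also counted across fractions, where no library is shared. Of genes at least 2-fold lower in ZnF1 in fraction B, 50 were higher (8.58 expected of independent lists) and 81 lower (14.82) in ZnF4 in fraction C, and of those higher in ZnF1, 23 were higher (8.01) and 38 lower (13.84). Of genes higher in ZnF1 in fraction C, 59 were higher (51.04 expected) and 443 lower (135.34) in ZnF4 in fraction B, and of those lower in ZnF1, 68 were higher (29.94) and 154 lower (79.4). Myeloid and erythroid genes, with medians of 3.74 and 3.85 in the ZnF1 library of fraction C, had medians of -1.74 and -1.30 in the ZnF4 library of fraction B. Polm, a polymerase of end joining, was at 7.3 RPKM in ZnF1, 45.6 in wt and 185.7 in ZnF4 in fraction B, and Adam19 at 5.1, 30.2 and 135.0.

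The 34 genes changed at least 2-fold in the same direction in both mutants and both fractions, such as Camk2b and Xist, were weighed against a pair of explanations. Sex-linked genes are argued against as the whole source, since 17.6% of the 34 (6 genes) lie on X or Y. DNA around Ikzf1 from another strain, carried along with the mutations, could account for some. Among genes past the filter, up to 100 on each side of Ikzf1 in gene order were taken. These were 163, since fewer than 100 lie on 1 side before the chromosome ends. Of the 28 autosomal genes, 2 were among them, Camk2b and Selm, where 0.43 were expected, which lies at percentile 92.7 of random sets. It cannot be told apart from chance with so few genes. Sparc, Snord91a, Col1a1 and Grb7 lie on the same chromosome, 157 to 600 genes from Ikzf1, and the remaining autosomal ones lie on others. That chromosome held 940 of the genes past the filter, and the chromosome as a whole was not tested. Effects of both fingers on the same genes stay open.

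For fraction C against B, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 limma calls (511 genes at an unadjusted p under 0.05) and the highest of the others 862. That number came from the splits that parted only the ZnF1 libraries and kept both wt and both ZnF4 libraries together. With a genotype term these splits reduce to 1 ZnF1 library against the other, so the number shows only that this pair differs more than the wt pair and the ZnF4 pair, a structure of the samples.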
